A study of Salmonella enterica with 9 samples.

How the data were processed

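RNA of 9 libraries, 3 for each of 3 media, was sequenced after removal of rRNA, ultrasonic fragmentation and preparation with a small RNA kit, per the labels' protocols. The only deposited file is a Cuffdiff table of differences between transcription start groups, with 13800 rows, that is 4600 start groups for each of 3 pairs of media. Reads were aligned with Bowtie2 (version 0.6 as listed) and processed with Cufflinks 2.2.1 and Cuffdiff, per the submitters' processing notes. The FPKM values, fragments per kilobase of transcript and scaled to mapped fragments, were made by the authors with Cuffdiff and deposited as 1 value per medium and start group. The log2 fold changes were deposited by the authors as the second medium over the first, and recomputing them from the FPKM values differed by at most 3.26e-05. The test statistic, a score, was deposited by the authors in the Cuffdiff output and was not used. The p-value and q-value of each row were deposited by the authors, the smallest p being 5e-05 and the smallest q 0.000230. Normalisation, dispersion settings, read filters and the masking of rRNA are not given in the sources used here. The authors tested 3470 rows and marked 10330 as not tested.

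Gene names, locus tags and coordinates came from the annotation of strain LT2 (assembly ASM694v2), whose locus tags the table uses, although the cells were of another strain of the same serovar. Of the 4600 start groups, 4598 matched it and 2 did not. There were 38 pseudogene rows, 1 row of signal recognition particle RNA and 1 of tmRNA besides the classes named below, and 7 rows joined several genes. A locus group shared by more than 1 start group occurred 505 times and covered 1216 rows. The 109 genes of the virulence plasmid were not analysed here. Reads of the rRNA operons, of repeated tRNA genes and of near-identical duplicates cannot be assigned to 1 copy, so single rows of these are uncertain. Coordinates are 1-based.

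The table has no value per library. The fallback fixed before the data were seen was therefore used for all 3 comparisons: no new test, with rows called at a q of at most 0.05 in the authors' deposited table. The q values assume that the 3 libraries of a medium are biological replicates, which the labels do not state. The split of calls was also computed after subtracting the median log2 fold change of tested protein-coding rows, with rows listed at 0 in 1 medium ranked as infinite. This split, and that under total-read scaling, only gives a new sign to rows already called. The q values test a difference from 0 in the authors' scaling and do not carry over. Rows not called there were not added. A list's calls were also counted after a Benjamini-Hochberg adjustment over its tested members alone.

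Read equivalents were recovered from the FPKM values. Each value was multiplied by an effective length for fragments of 200 bases (SD 80), the default of Cufflinks, and the 3 smallest steps in protein-coding rows of at least 800 bases were found per medium. A low value counted as on a step when within 1% of it. The effective step was 266 in minimal medium, 69.5 in tomato medium and 68.4 in root exudates, and FPKM times effective length over that step gave read equivalents summed over 3 libraries. For rows shorter than a fragment the equivalents depend on the effective-length model, whereas their ratio between media does not. Total-read scaling set the sum of read equivalents of all rows equal in each medium. Shares of lists in coding reads have 95% exact binomial (Clopper-Pearson) intervals, and ratios of genes have 95% intervals from the same exact model. The shares of protein-coding genes in all reads have 95% Wilson score intervals. All of these cover counting error only.

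A set of 45 gene lists was written before the data were seen. Members were matched by symbol, so genes annotated under another symbol were left out. These included mopA (groEL) and mopB (groES), which the heat shock and chaperone list held under other symbols. For each list the median difference of log2(FPKM + 1) over its members was compared with 10000 random lists drawn from the same 10 expression bins. The universe was 2471 protein-coding rows of at least 1 FPKM in a medium, and the 37 lists with 5 or more members in it got a percentile. Percentiles were not adjusted over the lists, and outside the central 95% of random lists 1.85 lists are expected per comparison. Random lists ignore operons, whose members are not independent. The named genes were the 10 largest and the 10 smallest finite log2 fold changes among calls with an absolute log2 fold change of at least 1, at least 10 FPKM in the higher medium and a symbol. Up to 5 rows listed at 0 in either medium, those with the highest FPKM, were added by a clarification made after the files were seen. Of each list described, up to 4 members were named, those with the smallest q and then the largest change. Genes named outside this rule were chosen after their values were seen.

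For the overlap, calls in both comparisons with minimal medium were counted. Counts for 3 unchanged media were drawn 100 times at the real depths for 2471 genes, and the covariance of the simulated fold changes was compared with the observed one. The methods were tested on simulated data. With 1783 simulated genes per medium, the steps were recovered within 0.0219% in minimal medium, 0.0172% in tomato medium and 0.0248% in root exudates, and 99.9% of the reads in each. With 2471 genes, 40 lists of 20 genes and 1000 random lists for each, an unshifted list fell outside the central 95% in 2 cases for tomato medium against minimal medium, 1 for root exudates against minimal medium and 5 for root exudates against tomato medium. A log2 shift of 0.5 was found for 16, 18 and 11 of the 40 lists in the same order, and a shift of 1 for 37, 36 and 37. For these lists the observed fold changes were permuted over genes and members were drawn at random. Operons and any tie to expression are thereby removed, so the rates do not carry over to real lists.

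The alternatives were a q of 0.01, an absolute log2 fold change of at least 1, minimums of 10 FPKM or 10 read equivalents, untested rows by fold change, centring on 2 kinds of median, total-read scaling, protein-coding rows only and rows above 0 in both media. For the lists they were pseudocounts of 0.1, 5 and 1 minimal medium read, no filter, a 10 FPKM filter, quantile normalisation, unmatched random lists and lists matched on length. Centring shifts a list and its random lists alike, so it gives the same percentile. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.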

Results

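Cells of Salmonella enterica serovar Typhimurium strain 14028s, a common laboratory strain, were grown overnight in LB broth at 37 °C, washed in 10 mM MgCl2 and set to an optical density of 1. Portions of 2 mL in dialysis tubes were then placed in 30 mL of 1 of 3 media. Minimal medium, the control, held glucose at 1.23 mM, with MgSO4 at 2 mM and M9 salts at 20%. Tomato medium held 25% plant extract and 20% M9 salts. The tomato root exudate medium was dried exudate from about 25 plants taken up in MgCl2. RNA was depleted of rRNA, fragmented and sequenced from 3 libraries per medium, 9 in all. The labels do not say how long the cells stayed in the media, nor whether the 3 libraries came from separate cultures, so the authors' tests may measure technical spread alone.

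The table analysed here gives 1 FPKM value per medium for each of 4600 transcription start groups of the LT2 chromosome (assembly ASM694v2), and the authors' Cuffdiff test for each pair of media. It holds no value per library, so no standard deviation is given and every q value below is that of the authors' deposited table. The groups comprised 4444 protein-coding rows, 85 tRNA rows, 22 rRNA rows and 7 rows of other small RNAs.

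The lowest FPKM values fell on discrete steps, which gave the read depth. Multiplied by effective length, the smallest values lay on 3 steps per medium, as 1 read in 1 of 3 libraries would give. Of the low values, 98.1% in minimal medium, 99.2% in tomato medium and 98.6% in root exudates lay within 1% of a step, whereas the steps covered 7.81%, 7.84% and 6.71% of the range. On this basis the 3 media had similar totals of about 7746320, 8235190 and 7445460 read equivalents. Protein-coding genes took only 12933 of these in minimal medium, or 0.167% (95% Wilson interval 0.164 to 0.170). They took 156736 (1.903%, 1.89 to 1.91) in tomato medium and 130482 (1.75%, 1.74 to 1.76) in root exudates. Reads of rRNA made up 96.3%, 93.7% and 90.0% of the totals in the same order. Of the 4444 protein-coding rows, 2483 were listed at 0 in minimal medium, 636 in tomato medium and 827 in root exudates. In minimal medium only 160 coding rows had 10 or more read equivalents. All intervals here cover counting error only.

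**Figure D1:**
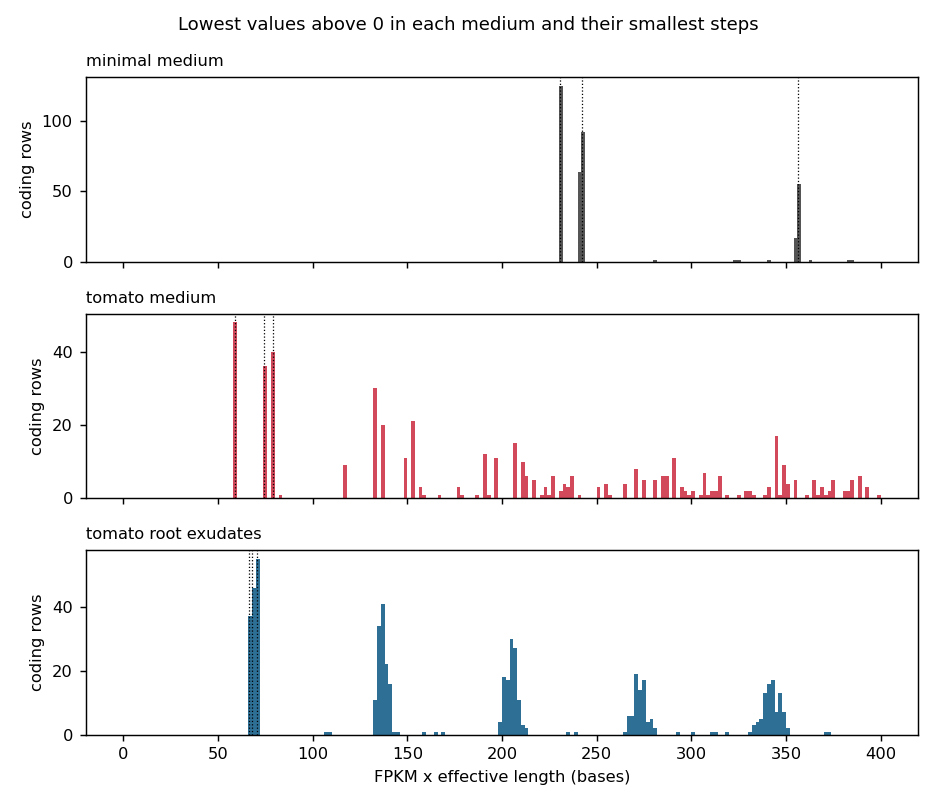
Histograms of FPKM multiplied by effective length (bases) for protein-coding rows of at least 800 bases, 1 panel per medium, up to 400 bases; the dotted lines mark the 3 smallest steps. The smallest steps lie at 231, 242 and 356 in minimal medium, at 58.8, 74.2 and 79.0 in tomato medium and at 66.4, 68.2 and 70.6 in root exudates, so 1 read stood for a larger FPKM in minimal medium.

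The authors' scaling shifted all comparisons with minimal medium. A read was worth 3.83 times as much FPKM in minimal medium as in tomato medium and 3.89 times as much as in root exudates. Tested protein-coding rows above 0 in both media had median log2 fold changes against minimal medium of 2.37 (tomato medium) and 1.96 (root exudates). The coding median used below includes rows listed at 0, which raises it, so rows between both medians change side. It was 3.34 in tomato medium against minimal medium and 2.98 in root exudates (5.19 and 4.997 under total-read scaling). Between root exudates and tomato medium the median was -0.51. Each direction is therefore given as deposited, and for both comparisons with minimal medium the split of the calls around these medians stands beside it where a list had more than 1. Such a split covers only rows called in the authors' scaling, and no row was tested against these medians. Between the tomato media that split equalled the deposited one in every list. Rows of rRNA were lower in both tomato media as deposited (median log2 fold change -1.91 and -2.11), but -0.06 and -0.09 when each medium was scaled to the same total of reads. Rows of tRNA had medians of -1.75 and -0.91 as deposited, and 0.09 and 1.11 under total-read scaling. The tRNA calls then split into 39 higher and 35 lower in tomato medium, and 52 higher and 6 lower in root exudates.

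**Figure D2:**
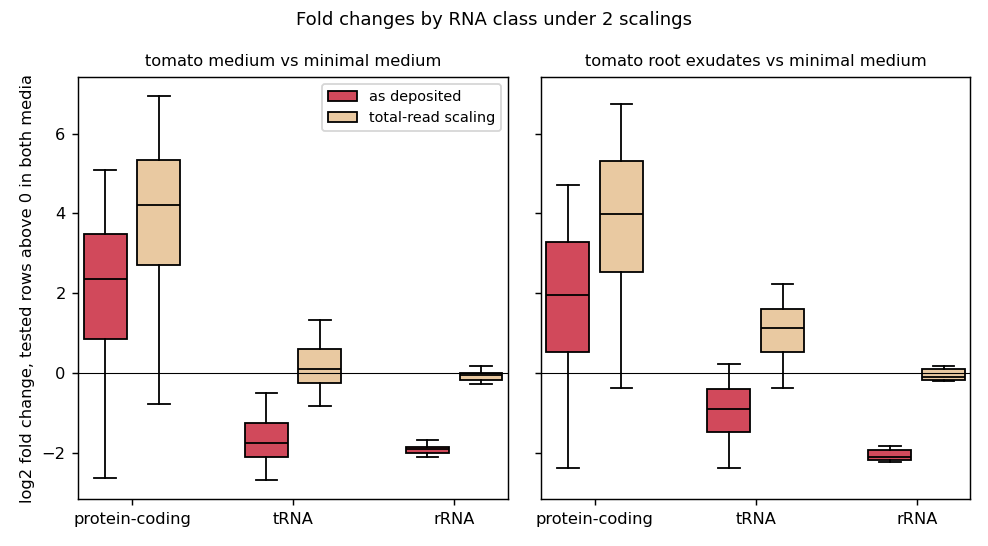
Log2 fold changes against minimal medium for tested rows above 0 in both media, by RNA class, in the authors' scaling (dark) and scaled to equal total reads (light); boxes span the quartiles, lines mark the medians and whiskers the 5th to 95th percentiles. Protein-coding rows lie above 0 under both scalings, with medians of 2.37 and 1.96 as deposited, while the rRNA boxes move to about 0 under total-read scaling.

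The first comparison asked how the tomato extract medium changed expression relative to glucose minimal medium. Higher in tomato medium were 14 of 16 tested glycolysis genes, 11 of 15 heat shock and chaperone genes, 29 of 54 ribosomal protein genes and 8 of 25 genes of anaerobic respiration and fermentation, where 479 of 1052 tested coding rows were higher in all. Of these calls 8 of 14, 8 of 11, 16 of 29 and 4 of 8 lay above the coding median. In the authors' deposited table yfiD, which encodes a stress-induced spare domain of pyruvate formate-lyase, was at 9.84 FPKM in minimal medium and 2116 FPKM in tomato medium, 215-fold higher (95% counting interval 101 to 520, q = 0.000230). The enolase gene eno was 87.2-fold higher (37.9 to 358) and gapA, for glyceraldehyde-3-phosphate dehydrogenase, 72.6-fold higher (33.5 to 172). Lower in tomato medium were the regulatory RNA csrB, which sequesters the regulator CsrA, at 11147 against 398 FPKM, the glycogen gene glgS, at 763 against 54.9 FPKM, and yfiA, for a ribosome-associated factor, at 680 against 60.9 FPKM.

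Of 1172 rows tested, 614 had q of at most 0.05 in the authors' deposited table, 481 higher and 133 lower in tomato medium. Among protein-coding rows 479 were higher, of which 285 were listed at 0 in minimal medium, and 32 were lower. Around the coding median the 511 coding rows split into 345 above and 166 below. All 22 rRNA rows and 74 of 85 tRNA rows were lower as deposited. Under total-read scaling the same 614 rows, not tested again, split into 537 above 0 and 77 below. The largest rises also included mopA (groEL, a chaperonin), clpB (a disaggregase), osmB, nifS (an iron-sulfur cluster gene), ahpF, ompA (an outer membrane porin) and deaD (an RNA helicase), between 32.3-fold and 50.0-fold. Minimal medium gave only 2 reads for osmB and for ahpF and 4 for eno, nifS and deaD. It gave 6 for mopA, 7 for yfiD and gapA, 10 for clpB and 12 for ompA. All these folds have wide intervals, such as 10.3 to 311 for ahpF and 18.7 to 63.4 for ompA. Among rows listed at 0 in minimal medium, ybeC reached 736 FPKM, rpmJ 400 FPKM, ptsH 197 FPKM, yhcN 196 FPKM and yjjY 149 FPKM in tomato medium. They held 352, 32, 194, 206 and 21 reads there, so a high FPKM of a short row can rest on few reads. The lower limits of the counting interval were only 2.14-fold for rpmJ and 1.36-fold for yjjY. The smallest fold changes, besides csrB, glgS and yfiA, were those of ybeL, ybfA, yejG and the tRNA genes leuX, leuU, tyrU and thrT, all of which stayed below 0 under total-read scaling. The rows zraP, yeeI and ydeW were listed at 0 in tomato medium and at 33.8, 17.8 and 11.5 FPKM in minimal medium.

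Glycolysis had 14 of 16 tested members higher (8 above and 6 below the coding median) and 15 past the threshold adjusted over the list alone, with a median at percentile 85.5 of 10000 random lists matched on expression. Its members eno, gapA, ptsG and ptsH, the last 2 listed at 0 in minimal medium, were among the rises. Ribosomal protein genes had 29 of 54 members higher, 16 above and 13 below the coding median (36 adjusted over the list alone), and their median lay at percentile 99.9. Examples listed at 0 in minimal medium were rpmA (70.9 FPKM in tomato medium), rplU (43.2 FPKM) and rpsD (31.9 FPKM). Heat shock and chaperone genes had 11 of 15 members higher, 8 above and 3 below the coding median (11 adjusted over the list alone, percentile 99.6, but 79.5 with a 10 FPKM filter), with dnaK, the main Hsp70 chaperone, rising 32.1-fold (20.6 to 56.7). They made up 4.08% of coding reads in tomato medium (95% interval 3.99 to 4.18) and 0.591% in minimal medium (0.463 to 0.735). Only 15 of the list's 20 symbols matched a row. The chaperonin rows mopA (groEL) and mopB (groES), with 1207 and 399 reads in tomato medium, are not in its counts, shares or percentiles. Genes of anaerobic respiration and fermentation had 8 of 25 tested members higher (8 adjusted over the list alone, percentile 100, but 56.2 with a 10 FPKM filter), of which 4 lay above the coding median and 4 below it. Among them pflB, for pyruvate formate-lyase, rose 25.9-fold (18.3 to 37.0), and adhE, for the alcohol dehydrogenase of fermentation, rose 10.1-fold (7.42 to 14.3), which is about the coding median (-0.01 from it on the log2 scale). All 8 arginine biosynthesis genes were tested and 6 were higher, all 6 above the coding median (6 adjusted over the list alone, percentile 99.8, but 82.0 with a 10 FPKM filter), including argA, argB, argE and argI, each listed at 0 in minimal medium. Of 5 tested hexose genes 2 were higher, both above the coding median (2 adjusted over the list alone). These fructose genes, fruK and fruF, were listed at 0 in minimal medium and at 24.4 and 38.1 FPKM in tomato medium, while the list as a whole lay at percentile 0.570 (7.53 with a pseudocount of 1 minimal medium read) with a median log2 difference of 0.46.

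Motility, iron, manganese and zinc uptake genes took a smaller share of coding reads in tomato medium, although their reads did not fall. Flagella and chemotaxis genes held 116 reads (0.895%, 0.742 to 1.07) in minimal medium and 380 reads (0.243%, 0.219 to 0.268) in tomato medium, with a list median at percentile 0.00 and 0 of 6 tested members past q of 0.05. Iron uptake genes held 208 reads (1.61%, 1.40 to 1.84) in minimal medium and 542 reads (0.346%, 0.317 to 0.376) in tomato medium. Of 7 tested, 3 were higher and 1 lower, 2 above and 2 below the coding median (4 adjusted over the list alone, percentile 0.00, but 15.8 with a 10 FPKM filter). Within them exbB, part of the energy supply of iron transport, was lower at 29.8 against 9.06 FPKM, although 0.13 higher on the log2 scale under total-read scaling. The ferrous iron transporter gene feoB was 4.41-fold higher as deposited and below the coding median, at -1.20. Manganese and zinc uptake genes held 92 reads (0.712%, 0.574 to 0.872) and 108 reads (0.0692%, 0.0565 to 0.0832) in the same order (percentile 0.00). Of 5 tested, only mntH, a manganese transporter gene, passed the threshold (1 adjusted over the list alone), lower at 4.64 against 1.23 FPKM (q = 0.0184), with 18 reads in each medium and a log2 fold change of -0.06 under total-read scaling.

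The second comparison set root exudates against minimal medium. Higher in root exudates were 5 of 7 tested genes of the glyoxylate shunt and acetate use, 12 of 18 of the general stress response and 23 of 51 of the ribosome, where 352 of 845 tested coding rows were higher in all. Above the coding median lay 5, 10 and 14 of these calls. In the authors' deposited table aceB (malate synthase), aceA (isocitrate lyase) and aceK (the kinase that regulates entry to the shunt) were listed at 0 in minimal medium and at 92.7, 61.1 and 67.6 FPKM in root exudates. The acetyl-CoA synthetase gene acs was 40.7-fold higher (12.6 to 379, q = 0.0194). The stationary-phase regulator gene bolA went from a listing at 0 to 239 FPKM. Lower in root exudates were csrB, at 11147 against 216 FPKM, the RNase P RNA rnpB, at 16578 against 545 FPKM, and ychH, at 266 against 12.4 FPKM.

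Of 968 rows tested, 476 had q of at most 0.05 in the authors' deposited table, 360 higher and 116 lower in root exudates. Protein-coding rows gave 352 higher, 199 of them listed at 0 in minimal medium, and 33 lower. Around the coding median they split into 262 above and 122 below, with 1 row equal to it. Under total-read scaling the 476 rows split into 436 higher and 40 lower. All 22 rRNA rows and 56 of 85 tRNA rows were lower as deposited, and 2 tRNA rows were higher. The largest rises were those of yiaG, at 69.0-fold (21.6 to 649), eno, at 41.8-fold (18.1 to 172), and ytfK, at 41.4-fold (14.8 to 140). After acs came yahO, the glutamate-binding gene gltI, ptsI (a phosphotransferase enzyme), pykF (pyruvate kinase), fusA (an elongation factor) and csrA, between 21.1-fold and 33.3-fold. All of these except fusA and ptsI had at most 4 reads in minimal medium. Among rows listed at 0 in minimal medium, ybeC reached 685 FPKM, yodD 649 FPKM, the pseudogene row rhoL 396 FPKM and yaiA 259 FPKM. They held 333, 448, 17 and 104 reads in root exudates. The smallest fold changes also included ucpA, the 5S rRNA row rrfE and the tRNA genes tyrU, leuX, leuZ, selC and cysT. The row yjiX was listed at 0 in root exudates and stood at 15.8 FPKM, or 2 reads, in minimal medium.

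The glyoxylate and acetate list had 5 of 7 tested members higher, all 5 above the coding median (5 adjusted over the list alone), and its median lay at percentile 100. It held 0.0549% of coding reads in minimal medium (0.0218 to 0.111), 0.196% in tomato medium (0.175 to 0.219) and 4.15% in root exudates (4.04 to 4.26). General stress and stationary-phase genes linked to the sigma factor RpoS had 12 of 18 tested members higher and 1 lower, 10 above and 3 below the coding median (13 adjusted over the list alone, percentile 99.9). Examples listed at 0 in minimal medium were osmE, at 95.6 FPKM, and osmC, at 23.6 FPKM. Ribosomal protein genes had 23 of 51 higher, 14 above and 9 below the coding median (26 adjusted over the list alone, percentile 99.2, but 92.4 with a pseudocount of 5), and glycolysis 11 of 13, 8 above and 3 below (12 adjusted over the list alone, percentile 65.0). The 8 histidine biosynthesis genes lay at percentile 99.6, with hisG, for the first enzyme of the pathway, past the threshold and above the coding median (1 adjusted over the list alone) and 6 reads for the whole list in minimal medium. The propionate gene prpB was listed at 0 in minimal medium and in tomato medium and was at 7.66 FPKM in root exudates. Iron uptake genes gave 2 higher and 2 lower of 8 tested, with the same split around the coding median (4 adjusted over the list alone, percentile 0.0300, but 11.5 with a 10 FPKM filter). Of these fhuA, a ferrichrome receptor gene, was 8.77-fold higher (3.96 to 29.3), and exbB and fes were lower as deposited but 0.48 and 0.05 higher on the log2 scale under total-read scaling. Flagella and chemotaxis genes lay at percentile 0.00 (2.65 without a filter) with 0 of 6 past q of 0.05. Anaerobic genes lay at percentile 0.00500 (3.53 with a 10 FPKM filter), yet 4 of 8 tested were higher and 1 lower, 2 above and 3 below the coding median (5 adjusted over the list alone). The higher ones included pflA, listed at 0 in minimal medium, fnr, for the regulator of anaerobic growth, at 7.76-fold (2.96 to 29.0), and pflB, at 3.36-fold (2.33 to 4.84), the last 2 below the coding median at -0.02 and -1.23, and the lower one was hypA. Maltose and glycerol genes lay at 0.120 (7.78 without a filter), with malM lower at 8.77 against 0.956 FPKM as the only member tested (1 adjusted over the list alone). Manganese and zinc uptake lay at 0.720, with 1 of 5 lower (0 adjusted over the list alone), mntH at 4.64 against 1.89 FPKM, which was 0.72 higher on the log2 scale under total-read scaling.

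Among 652 protein-coding rows tested against minimal medium in both tomato media, 235 were higher in both, 14 were lower in both and 2, rmf and STM1988, went in opposite directions. Without rows listed at 0 in minimal medium 103 were higher in both. Both comparisons use the same minimal medium libraries, so this overlap may come from them, and the table has no values per library with which to split them. Across 2471 coding rows the covariance of the log2 fold changes, each centred on its median, was 1.56. In 100 simulations of unchanged media with counting error alone it was 0.58 (SD 0.0356), a difference of 0.98. The correlation across genes was 0.62 and its simulated value 0.83, and 64.0% of rows had the same sign against a simulated 83.4%.

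The third comparison set root exudates directly against tomato medium, whose depths were alike. Lower in root exudates were 11 of 15 tested heat shock genes, 8 of 8 arginine genes, 10 of 19 aerobic respiration genes and 8 of 25 anaerobic genes. Of 19 tested RpoS-linked genes 10 were higher and 4 lower, and of 9 glyoxylate and acetate genes 1 was higher and 2 lower. In the authors' deposited table dnaK (bases 11593 to 13509) was at 86.9 FPKM in tomato medium and 2.43 FPKM in root exudates, a ratio of 0.0279 (0.0213 to 0.0361, q = 0.000230). The peroxiredoxin gene ahpC (670452 to 671015) was at 123 against 2.30 FPKM, and cydA (809532 to 811100), for a subunit of cytochrome bd oxidase, at 26.7 against 1.09 FPKM. In the other direction yahO was 29.9-fold higher in root exudates (18.3 to 49.6), ytfK 26.5-fold (17.3 to 42.6) and rpoS (3065501 to 3066493), the stress sigma factor gene, 3.14-fold (2.89 to 3.43).

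Of 1330 rows tested, 424 had q of at most 0.05 in the authors' deposited table, 180 higher and 244 lower in root exudates. These comprised 134 higher and 235 lower coding rows, 44 higher and 7 lower tRNA rows and no rRNA row, of which none of 22 passed an unadjusted p of 0.05 either. Around the coding median and under total-read scaling the coding split was the same, 134 to 235. At q of at most 0.01 there were 261 rows, 114 higher and 147 lower. Besides those named, the largest falls were those of ydiH, mopA, ibpA (a small heat shock protein gene), fruA (the fructose transporter gene), mopB (groES), artJ (an arginine-binding protein gene) and cydB, with ratios of 0.0204 to 0.0502. The largest rises were also cutC, ybgS, aldB (an aldehyde dehydrogenase gene), ymgE, sfsA, yjbJ, yodD and bolA, between 7.72-fold and 26.4-fold. Listed at 0 in root exudates were ybiJ, yddX, glnK, hypA and yehE, at 17.0 to 25.5 FPKM in tomato medium.

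**Figure D3:**
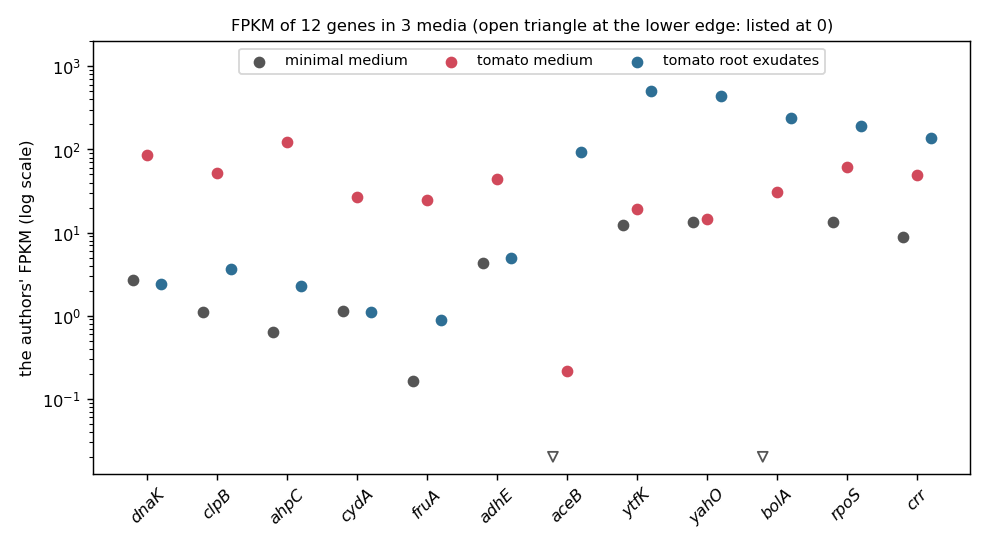
The authors' FPKM (log axis) of 12 genes in minimal medium (grey), tomato medium (red) and root exudates (blue); an open triangle at the lower edge marks a gene listed at 0, and no error is drawn because the table has 1 value per medium. For dnaK, clpB, ahpC, cydA, fruA and adhE the tomato medium value lies above both others, and for aceB, ytfK, yahO, bolA, rpoS and crr the root exudate value does; genes were chosen after their values were seen.

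Heat shock and chaperone genes had 11 of 15 members lower and 1 higher in root exudates (13 adjusted over the list alone, percentile 0.00). The ratios were 0.0695 for clpB, 0.0801 for htpG and 0.132 for hslU. Their share of coding reads was 0.835% (0.786 to 0.885) in root exudates against 4.08% in tomato medium. Both shares leave out mopA and mopB. Anaerobic respiration and fermentation genes had 8 of 25 lower and none higher (8 adjusted over the list alone, percentile 0.00), with adhE at 43.6 against 4.96 FPKM and the hydrogenase genes hycB, hycC and hypA listed at 0 in root exudates. All 8 arginine biosynthesis genes were lower (8 adjusted over the list alone, percentile 0.150, but 16.8 with a 10 FPKM filter), among them argC, with a ratio of 0.140 (0.0927 to 0.204), and argB, with 0.161. Aerobic respiration genes had 10 of 19 lower and none higher (10 adjusted over the list alone, percentile 0.915), including nuoC, a subunit gene of NADH dehydrogenase, with a ratio of 0.241. Ribosomal protein genes had 17 of 54 lower and none higher (17 adjusted over the list alone, percentile 0.0400), with ratios of 0.133 for rplA and 0.398 for rplT. Of 11 tested genes of the oxidative stress list 6 were lower and 1 higher (7 adjusted over the list alone, percentile 4.70). Its members ahpF, dps (an iron-storing DNA-binding protein gene) and grxA (glutaredoxin) fell, and acnA (aconitase A) rose. The fructose genes fruA and fruK were the 2 of 6 tested hexose genes that fell (4 adjusted over the list alone, percentile 38.0). Nitrogen limitation genes had 4 of 13 lower and none higher (4 adjusted over the list alone, percentile 13.4), namely glnK, glnH, glnA (glutamine synthetase) and amtB (the ammonium channel gene).

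RpoS-linked stress genes had 10 of 19 members higher and 4 lower (14 adjusted over the list alone, percentile 99.96, but 96.1 with a 10 FPKM filter). The rises included bolA, from 30.9 to 239 FPKM, and the falls included dps, from 85.1 to 21.1 FPKM, and osmB, from 560 to 187 FPKM. This list held 1.85% of coding reads (1.78 to 1.92) in tomato medium and 4.26% (4.15 to 4.37) in root exudates. The glyoxylate and acetate list lay at percentile 100, but only 1 of its 9 tested members was past the threshold upwards, the acetate permease gene yjcG at 9.45-fold (5.29 to 20.3), and 2 were past it downwards, pta and ackA, which make and use acetyl phosphate (3 adjusted over the list alone). The operon of aceB, aceA and aceK (4402052 to 4407213) held 4, 5 and 7 reads in tomato medium and 1900, 987 and 1901 in root exudates, yet its q values were 0.136, 0.123 and 0.102; aceB and aceA were chosen here after their values were seen. Further genes past the threshold upwards were pps (phosphoenolpyruvate synthase, 5.92-fold), fadD (fatty acyl-CoA synthetase, 7.37-fold), the phosphate starvation gene phoH (5.20-fold), fhuA (12.7-fold) and the trehalose genes otsA (3.60-fold) and otsB (4.24-fold). The lists lay at percentile 98.25 for fatty acid degradation (1 of 2 tested higher, 1 adjusted over the list alone), 99.7 for phosphate starvation (1 of 2, 1 adjusted over the list alone) and 98.4 (95.5 with a pseudocount of 5) for osmotic stress (3 of 6 higher and 1 lower, 4 adjusted over the list alone). The porin gene ompC, counted in the osmotic list, fell from 58.7 to 6.76 FPKM. Gluconeogenesis, the list of pps, lay at percentile 84.2, with 1 of 3 tested members higher and 1 lower (2 adjusted over the list alone). Within glycolysis gapA, tpiA and eno fell while crr, for a glucose phosphotransferase subunit, rose 2.78-fold (2.38 to 3.25), and 8 members passed adjusted over the list alone (percentile 19.6). RNase P RNA, rnpB, fell from 4231 to 545 FPKM.

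Virulence genes had few reads. The type III secretion genes of pathogenicity island SPI-1 had 5, 135 and 47 reads in minimal medium, tomato medium and root exudates for 36 rows, and those of SPI-2 had 23, 157 and 91 reads for 38 rows. The only member past the threshold was hilC, a regulator gene of SPI-1, which was listed at 0 in minimal medium and at 3.39 FPKM in tomato medium. Against 0.206 FPKM in root exudates its q was 0.282. The SPI-1 genes made up 0.0863% of coding reads in tomato medium (0.0722 to 0.102) and 0.0357% in root exudates (0.0265 to 0.0479). The percentile of their list rested on only 5 members, those of at least 1 FPKM in a medium. It was 99.2 in tomato medium against minimal medium and 0.190 in root exudates against tomato medium. With a pseudocount of 1 minimal medium read it was 13.0 and 56.0.

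**Figure D4:**
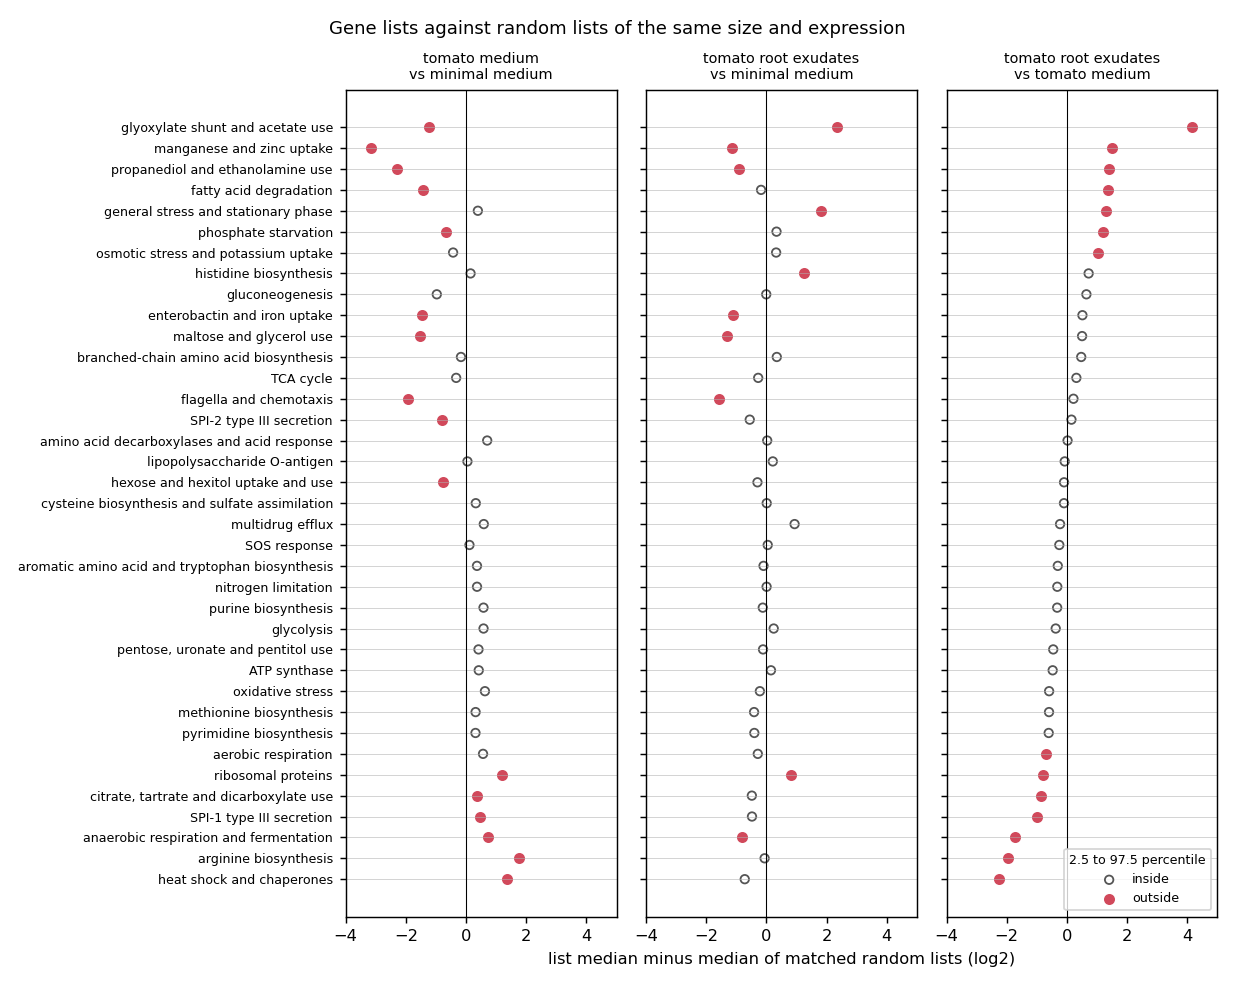
Median difference of each gene list (log2 of FPKM plus 1) minus the median of matched random lists, for 37 lists and 3 comparisons; filled points lie outside the central 95% of 10000 random lists. Outside it lie 16, 10 and 14 lists in the panels from left to right, where 1.85 are expected by chance in each, and members of 1 operon are not independent. With fold changes permuted over genes, 2, 1 and 5 of 40 unshifted lists lay outside in the same order. The permutation removes operons and ties to expression, so it gives no error rate for real lists.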

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

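The explanations weighed in this part and the bounds set for them were chosen after the results had been seen, and the bounds for few reads and for the tRNA rows were changed once their first values were known, while the gene lists and their comparison with random lists were fixed before. In 3 rows the tomato media differed from minimal medium in opposite directions in the authors' deposited table, each with a q of at most 0.05 in all 3 comparisons. The ribosome modulation factor gene rmf stood at 2472 FPKM in minimal medium, 1096 FPKM in tomato medium and 4587 FPKM in root exudates, with a log2 fold change of 2.07 between both tomato media (q = 0.000230). Under total-read scaling it was higher than in minimal medium in both (0.67 and 2.91), and relative to the coding median lower in both (-4.52 and -2.09), so only the difference between the tomato media keeps its direction. The tRNA row STM1262 stood at 7116, 1587 and 14037 FPKM, with a log2 fold change of 3.14 between both tomato media (q = 0.0108). The protein-coding row STM1988 stood at 81.5, 21.0 and 216 FPKM, with 3.36 (q = 0.00124). For both, values under total-read scaling kept opposite signs (-0.32 and 2.998, -0.11 and 3.42), and both were below the coding median in each tomato medium. In minimal and tomato medium STM1262 held 38 and 32 reads and STM1988 18 and 18. The negative values thus rest on near-equal counts and do not show a fall in tomato medium under that scaling.

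Protein-coding rows were higher in both tomato media than in minimal medium, and scaling, rRNA removal or loss of mRNA could each give this. Scaling does not account for it, since the coding share of reads, which needs no scaling, was at least 10.5 times as high in the tomato media. Incomplete rRNA removal does not account for all of it, because coding reads per tRNA read were at least 3.98 times as high. Coding reads per tmRNA read were 4.36 times as high or more, but the table and labels give no added RNA standard or RNA quality value, so mRNA lost in preparation cannot be told from less mRNA in the cells. The minimal medium samples are numbered apart from those of both tomato media. Whether they were also prepared or sequenced apart was not examined, and such a difference could not be told from the medium. Whether scaling accounts for the 74 lower tRNA rows in tomato medium cannot be told. Under total-read scaling 24 stayed below 0 by their counting intervals (1.85 expected), which leave out any spread between libraries. By the spread taken from the authors' p values 1 did. These p values have a lower limit, so that spread is an upper limit and the 1 a lower limit. It therefore does not weigh against the 24.

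The median of the heat shock and chaperone list was lower in root exudates than in tomato medium (11 of 15 tested members lower, 1 higher), and scaling, few reads or a difference in growth could each give this. The list median lay -2.25 from that of matched random lists, which share any scaling. Of all 15 tested members, 11 had a counting interval below the coding median where counting error alone gives 0.375 (binomial p = 2.97e-15). The list was weighed after 11 members had been called lower, so this outcome was largely set beforehand. The binomial p also treats members as independent and gives each exactly the median fold, so it carries no weight for the list. The intervals show only that counting error does not place those 11 below the median. Few reads stay open for the other 4 members. The list lay -1.53 from the median of the ribosomal protein genes, of which 17 of 54 tested were lower and 0 higher. A shift of equal size in both lists is therefore too small. Growth could move both lists by unlike amounts and was not measured, so a difference in growth stays open. The media are the only biological difference in the labels, and the heat shock response itself was not measured otherwise.

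The medians of the glyoxylate and acetate list (1 of 9 tested members higher, 2 lower) and of the RpoS-linked list (10 of 19 higher, 4 lower) were higher in root exudates than in tomato medium. Scaling does not account for this, as the lower of both list medians lay 1.31 above random lists. The operon of aceB, aceA and aceK does not alone decide the first list, which stayed at percentile 100 without it. Only 6 members were then left, among them pta and ackA, both lower. Random lists ignore operons, and whether a further operon carries these 6 was not tested. A single library might carry the operon's difference, as its q of 0.102 for aceK at 1901 reads against 7 allows. Without values per library this cannot be told. Such a q also occurred with fewer reads in the lower medium. In tomato medium against minimal medium cysK, at 486 reads against 1, had a q of 0.105, but ahpF, at 287 against 2, had 0.0229. Rows with as few reads as the operon had smaller q values. There gapA, at 1854 reads against 7, had 0.000230, and in root exudates against tomato medium cutC, at 181 against 7, had 0.0461. Few reads in the lower medium therefore need not give such a q, and unlike libraries stay open. The operon's q of 0.000230 against minimal medium was shared by 144 of 243 tested coding rows listed at 0 there, down to 16.1 reads. The media are the biological explanation the design offers, and it was not tested apart from growth phase or time in the medium.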

How the results depend on the processing

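No paired analysis was possible because the table gives no value per library. For the same reason linear-model fits, replicate blocks, leaving out single libraries, fits of 2 groups, count tools and list tests with an estimated correlation were not run. Total-read scaling, centring on coding rows, the read-equivalent and coding-only filters, rows above 0, the pseudocount of 1 read and length matching were chosen after the data were seen. Of 12 counts, 82 values stayed within 1.5 times the main one and 22 did not. For tomato medium against minimal medium, a minimum of 10 FPKM left 359 calls (233 higher) and rows above 0 in both media 321 (194 higher). The lower calls were 241 when centred on tested rows, 267 when centred on coding rows, 77 under total-read scaling and 32 among coding rows only. Centring and total-read scaling changed only the sign of calls already made, with the same q values. For root exudates against minimal medium the same settings gave 287 (182 higher), 267 (156 higher), and 175, 208, 40 and 33 lower. For root exudates against tomato medium, q of at most 0.01 left 261 calls (114 higher, 147 lower), and 10 FPKM left 148 lower. Rows higher in both tomato media and above 0 in minimal medium numbered 103. With a 10 FPKM filter 7 list results lay outside the central 95% of random lists, as only 10 lists kept 5 members. Filters lower counts because they leave fewer rows. Of 111 list results, 73 kept their side under every setting, and of the 40 outside, 16 stayed so. The list of SPI-1 genes reversed with a pseudocount of 1 read, to percentile 13.0 for tomato medium against minimal medium and 56.0 for root exudates against tomato medium. That of citrate and tartrate genes reversed without a filter, to 42.3 and 70.3, and the cause was not tested. The other 20 left the outer 5% under some setting, with these farthest percentiles. For tomato medium against minimal medium they were 79.5 for heat shock, 56.2 for anaerobic, 82.0 for arginine, 15.8 for iron, 21.2 for SPI-2, 19.3 for phosphate, 14.3 for glyoxylate and acetate, 7.53 for hexose and 47.0 for propanediol and ethanolamine genes. For root exudates against minimal medium they were 92.4 for ribosomal, 2.65 for flagella, 11.5 for iron, 7.78 for maltose, 3.53 for anaerobic and 50.0 for propanediol and ethanolamine genes. For root exudates against tomato medium they were 16.8 for arginine, 96.1 for RpoS-linked, 95.5 for osmotic, 96.5 for manganese and zinc and 50.4 for propanediol and ethanolamine genes. Of 118 gene results 110 kept their direction. The others were feoB (-0.83 and -1.20 when centred on tested and coding rows) and adhE (-0.00557, coding rows) for tomato medium against minimal medium, pflB (-0.80 and -1.23) and fnr (-0.0224, coding rows) for root exudates against minimal medium, and, under total-read scaling, exbB (0.13 in tomato medium, 0.48 in root exudates), fes (0.0494, root exudates) and mntH (0.72, root exudates), which the subtracted shift alone produces. The coding rows of this centring include those listed at 0. Against the median of coding rows above 0 in both media, adhE (3.34 against 2.37) and fnr (2.96 against 1.96) were higher. Against the same medians feoB (2.14) and pflB (1.75) stayed lower. Against the change of all coding reads in the authors' scaling (1.66 in tomato medium, 1.37 in root exudates) all of these were higher. Depth limited minimal medium most, where 160 coding rows had 10 or more reads.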

Other observations

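Abundant RNAs differed between the media in the authors' deposited table, and those named here were chosen after their values were seen unless named above. The lipoprotein gene lpp, for the most abundant outer membrane lipoprotein, stood at 4718 FPKM in minimal medium, 4675 in tomato medium and 907 in root exudates, and fell by 2.37 on the log2 scale between both tomato media (q = 0.000230). RNase P RNA, rnpB, held 11024, 10767 and 1412 reads in the same order. The regulatory RNA csrB held 6508, 889 and 492 reads, while csrA, for the RNA-binding regulator that csrB sequesters, stood at 31.6, 133 and 665 FPKM, with 3, 47 and 240 reads. The heat shock sigma factor gene rpoH stood at 1.82, 19.5 and 11.6 FPKM, a smaller difference between both tomato media (-0.75, q = 0.0423) than that of dnaK (-5.16). The cold shock gene cspA fell by 1.53 on the log2 scale between both tomato media (q = 0.00142). The manganese and iron transporter genes sitA, sitB, sitC and sitD stood at 0.639, 0.127, 0.643 and 0.213 FPKM in tomato medium and at 5.86, 4.64, 4.49 and 4.65 FPKM in root exudates, all with q above 0.05, and the manganese and zinc list lay at percentile 99.9 for that pair.

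Amino acid and nucleotide lists other than arginine gave few calls. In tomato medium against minimal medium, 3 of 3 tested branched-chain, 3 of 3 pyrimidine, 2 of 2 purine, 2 of 4 aromatic, 2 of 11 cysteine, 1 of 3 methionine and 1 of 4 histidine genes were higher and none lower. In root exudates against tomato medium, 3 of 11 cysteine, 1 of 3 pyrimidine and 1 of 2 purine genes were lower, and none of 3 methionine (3 adjusted over the list alone, percentile 4.40), 4 branched-chain, 4 aromatic and 8 histidine genes was called. In tomato medium against minimal medium the tricarboxylic acid cycle had 3 of 7 tested members higher, ATP synthase 3 of 5, aerobic respiration 7 of 19, gluconeogenesis 1 of 2, oxidative stress 4 of 10, nitrogen limitation 5 of 12, SOS response 2 of 4, osmotic stress 2 of 3, acid response 2 of 3, multidrug efflux 3 of 6, O-antigen 3 of 10 and pentose use 3 of 4, with none lower and all inside the central 95% of random lists. Adjusted over each list alone these counts differed only for methionine (2), aromatic (3), oxidative stress (5), nitrogen limitation (6), multidrug efflux (4) and O-antigen (2). Around the coding median the calls in tomato medium against minimal medium split into 0 above and 3 below for the tricarboxylic acid cycle, 1 and 2 for pyrimidines and for pentose use, 1 and 1 for purines, cysteine and osmotic stress, 2 and 1 for branched-chain amino acids, efflux and O-antigen, 5 and 2 for aerobic respiration, 3 and 1 for oxidative stress and 4 and 1 for nitrogen limitation, and all lay above it in the other lists of this paragraph so far. RpoS-linked genes had 7 higher and 1 lower of 13 tested there, 6 above and 2 below the coding median (percentile 82.2). Heat shock genes in root exudates against minimal medium had 5 of 8 higher, of which 1 lay above the coding median, 3 below and 1 on it (percentile 10.9). The phosphate list lay at percentile 2.35 in tomato medium against minimal medium with none tested, fatty acid degradation at 1.18 with 1 of 2 lower, maltose and glycerol at 0.2 with 0 of 1 called, and propanediol and ethanolamine at 0.00 with 0 of 1 called. Under an alternative the phosphate list moved as far as 19.3 and the propanediol and ethanolamine list as far as 47.0. Citrate and tartrate genes lay at 97.7 with 1 of 2 higher, SPI-1 genes at 99.2 with 1 of 1 higher, SPI-2 genes at 1.63 and glyoxylate and acetate genes at 1.61, both with 0 of 2 called (0 and 2 adjusted over the list alone). Citrate and tartrate genes moved to 42.3 without a filter, and SPI-1 genes to 13.0 with a pseudocount of 1 minimal medium read. The farthest percentiles under an alternative were 21.2 for SPI-2 and 14.3 for glyoxylate and acetate genes. Propanediol and ethanolamine genes lay at 0.260 in root exudates against minimal medium and at 99.3 in root exudates against tomato medium, with no call. Under an alternative these moved as far as 50.0 and 50.4. In root exudates against tomato medium SPI-1 genes lay at 0.190 (56.0 with a pseudocount of 1 minimal medium read), with no call. Citrate and tartrate genes lay at 0.445 there (70.3 without a filter), also with no call, and iron uptake genes at 91.7 with 1 of 8 higher and 1 lower. For PhoPQ genes 2, 1 and 2 members were tested in the 3 comparisons and for curli and cellulose 0, 1 and 1, with no call. Copper genes had 1 of 1 higher in tomato medium against minimal medium, below the coding median, and 1 of 1 lower in root exudates against tomato medium. Of the propionate list 1 of 1 tested gene, prpB, was higher in root exudates against each other medium. None of 48 fimbrial rows was tested, 1 of 15 prophage symbols matched a row, which was untested, and none of 16 myo-inositol symbols matched. Genes of these 2 lists that the table gives under locus tags alone were not examined. Of the structural RNA list 23 of 23 tested rows were lower in both tomato media against minimal medium as deposited, and 1 of 23, rnpB, was lower in root exudates against tomato medium.

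As a hypothesis, the higher median of the glyoxylate and acetate list in root exudates could be part of a wider use of fatty acids, propionate and gluconeogenic carbon. The lists of these 3 functions, joined to 14 genes, had a median log2 difference of 1.18 between root exudates and tomato medium, at percentile 100, but lay at percentile 85.6 against minimal medium, so the test left it open. As a further hypothesis, the labels list M9 salts for tomato medium but not for root exudates, so phosphate or ammonium could be scarcer there. Phosphate starvation genes lay at percentile 99.7 against tomato medium but at 90.1 against minimal medium, which also has M9 salts. Between the media that share these salts they lay at 2.35, but as far as 19.3 under an alternative, with no member tested. The first therefore stays open. Nitrogen limitation genes lay at percentile 13.4 against tomato medium and at 50.6 against minimal medium, on the side opposite to the second in the former, so it was not borne out. Metabolite levels were not measured, and all 3 tests were chosen after the results had been seen and their bounds changed once, with the comparison against minimal medium added, when their first values were known.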
